A study of Rattus norvegicus with 8 samples.

How the data were processed

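Total RNA from rat hippocampal slice cultures was profiled on 8 Affymetrix-type expression arrays. Per the labels, each array holds RNA pooled from 15 cultures from which a hippocampal field, CA1 or CA3, had been dissected, with a time of 7 days. The labels put 3 arrays in the CA1 control group, 3 in the CA3 control group, 1 in the CA1 lesion group and 1 in the CA3 lesion group, and these labels were the only source of the groups. Neither the kind of lesion nor the event from which the days were counted is given in the labels.

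The deposited values are linear signal intensities, with 1 value per probe set and array. Every array of the deposited table had a 2% trimmed mean close to 2501, from which the values were taken to be scaled to a common level by the authors. The software, its version and the way probes were summarised are not given in the sources used here. Detection calls and probe-level values were not used here. Arrays have no sequencing depth, and their number limits the precision of every comparison.

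Intensities were kept at the deposited scaling and converted to log2(value + 16), so a fold change is on that scale and understates the change of dim probe sets. Of 31099 probe sets, 57 control probe sets were removed. Probe sets whose mean log2 value over the 8 arrays lay under the 40th percentile were also left out, and 18625 were tested. Gene names came from the platform annotation, in which 20832 probe sets have 1 gene symbol, 436 have several and 9831 have none. Of the probe sets with 1 symbol, 20764 matched a rat gene of the RefSeq table for the GRCr8 assembly by gene identifier, and 0 symbols changed. No gene was named from a probe set with several symbols. The files name no genome build, so no coordinates are given.

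A linear model with 1 coefficient per group was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean intensity and 4 residual degrees of freedom. The spread came from the controls, since each lesion group is a lone array that is assumed to vary like the controls. The 5 contrasts were CA3 minus CA1 controls, the mean lesion effect over both regions, the lesion effect in CA1, the lesion effect in CA3, and the CA3 lesion effect minus the CA1 lesion effect. P-values were adjusted by the Benjamini-Hochberg method over the probe sets tested, with a threshold of 0.05. Nothing in the labels says that the samples came from separate animals or culture preparations, so p-values measure only the spread between these samples, which may be technical.

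Before the data were examined, 25 gene lists were fixed for cell types, hippocampal fields and pathways, along with the tests, the alternatives and the rule for named genes. Lists were tested with limma's camera, with a preset correlation of 0.01 between genes and adjustment over the 25 lists of a contrast. Each gene entered with its brightest probe set, which gave 10844 genes. The same test was run with the correlation estimated from the residuals, and members were also adjusted over the list alone. Genes named for the region contrast are the 12 per direction with the largest difference past the threshold whose control arrays did not overlap between regions, whose higher mean lay above the median of all probe sets, and which had 1 gene symbol. For the lesion contrasts the lesion array had to lie beyond all 3 controls of its region. Where fewer than 5 genes per direction passed, the 5 with the smallest p under the other conditions are named as not past the threshold. For the difference of the lesion effects the rule fixed in advance did not spell out this condition, and it was taken to mean that the CA3 lesion array lay beyond all its controls while the CA1 lesion array did not lie beyond its own in the same direction. Up to 4 members per list are named by their p, and those few added for other reasons are said to be.

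Alternatives were quantile normalisation, pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, no intensity trend in the variances, removal of probe sets with possible cross-hybridisation, the replicate number as a block, each array left out in turn, the 6 control arrays alone, an additive model for the lesion, and the mean of all probe sets of a gene. Fits without control 1 of both regions, and without control 3 of both regions, were added after the data were seen.

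The fit was run on simulated arrays with the real means, in which 200 of 18625 probe sets were changed, in 20 rounds. Their spread was drawn from the variance model of the fit itself, and lesion arrays varied like controls. For the region contrast the fit recovered 13.1% of 2-fold, 56.6% of 4-fold and 72.7% of 8-fold changes, and 5.30% of its calls were false. For the mean lesion contrast it recovered 14.0%, 58.5% and 75.6%, with 5.29% false calls. These shares hold only if that variance model is right, and they test neither the model nor the assumption that lesion arrays vary like controls. With 10844 simulated genes and the microglia list raised by 1 log2 unit in the lesion arrays, camera called that list in 20 of 20 rounds and made 6 calls in 480 tests of the other lists. The simulated genes varied independently of each other and carried no difference by replicate number. These counts therefore do not show how often the preset correlation gives false calls for lists whose genes move together.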

Results

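Gene expression was measured in CA1 and CA3, the main pyramidal cell fields of the hippocampus, dissected from rat slice cultures, which are thin explants of hippocampus kept alive in a dish. There were 3 control arrays for each field and a single lesion array for each field, all at 7 days and each from 15 cultures. The labels state no aim, and the design allows a comparison of CA3 with CA1 in the controls, of lesion with control in each field, and of the lesion effects between the fields.

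Array signal was similar in level across the 8 arrays. The median intensity ran from 561 for CA3 control 3 to 815 for CA1 control 2. Log2 values correlated at 0.834 to 0.908 between arrays, across probe sets, which are not independent replicates, and CA1 control 2 had the lowest mean correlation with the others, 0.846. The 3'/5' signal ratio of the Gapdh control probe sets, which rises as RNA degrades, was 3.71, 4.98 and 5.0 in CA1 controls 1 to 3 and 3.84, 3.75 and 3.93 in the CA3 controls. It was 4.65 in the CA1 lesion array and 5.23 in the CA3 lesion array, the highest of the 8 and above all CA3 controls. The CA3 lesion comparison was therefore not matched in this ratio. The comparison of CA3 with CA1 controls was not fully matched either, since CA1 controls 2 and 3 lay above all CA3 controls and CA1 control 1 below them. The same ratio for Actb ran from 14.5 in CA1 control 1 to 22.2 in CA1 control 2, with 17.3 and 19.8 in the CA1 and CA3 lesion arrays. CA3 controls 1 to 3 had Actb ratios of 21.4, 20.3 and 15.0, a range that holds the CA3 lesion array.

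Control cultures of CA3 and CA1 kept distinct expression profiles. Pou3f1, a POU-domain transcription factor, was 23.0-fold higher in CA1, with a log2 difference of -4.52 ± 0.42 (SE, n = 3 arrays per field, limma adjusted p = 0.00305). Fibcd1 and Mpped1 were 14.5-fold and 12.9-fold higher in CA1. The largest difference in the other direction was that of Ptgds, which encodes a prostaglandin D synthase, at 50.7-fold higher in CA3 (5.66 ± 0.52, SE, n = 3 per field, limma adjusted p = 0.00305, and 4.91 without CA1 control 1). Kcnq5, a subunit of M-type potassium channels, was 5.43-fold higher in CA3 by the probe set named here (2.44 ± 0.30, adjusted p = 0.00748), while its other probe set differed by 0.29 ± 0.73 (adjusted p = 0.944).

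In all, 98 probe sets passed the threshold in limma, 53 higher in CA3 and 45 lower. Among genes higher in CA3, Tmem71 differed 10.6-fold, the protease inhibitor Cst6 8.77-fold, the calcium-dependent membrane-binding protein Cpne4 8.45-fold (3.08 on the log2 scale, 2.49 without CA1 control 2) and Islr2 7.61-fold. Nnat was 5.90-fold higher, lipoprotein lipase (Lpl) 5.84-fold, Plcxd2 5.29-fold, Itgbl1 5.26-fold, Islr 5.19-fold and the apelin receptor Aplnr 4.74-fold. Among genes higher in CA1, the adhesion receptor Adgrl2 differed 10.3-fold, the cardiac myosin heavy chain Myh7 10.3-fold, the transcription factor Bcl11b 8.24-fold and Ldb2 7.61-fold. Ankrd63 was 5.27-fold higher in CA1, the serotonin receptor Htr5b 5.04-fold, Rasl11b 4.52-fold, the neuropeptide cholecystokinin (Cck) 4.46-fold and Gpr161 4.35-fold. Other probe sets of Plcxd2 and Bcl11b also passed, at 2.33 and -2.32, whereas that of Gpr161 differed by -0.95 (adjusted p = 0.638). The adjusted p-values of the 24 named genes ran from 0.00144 for Mpped1 to 0.0323 for Myh7.

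**Figure D1:**
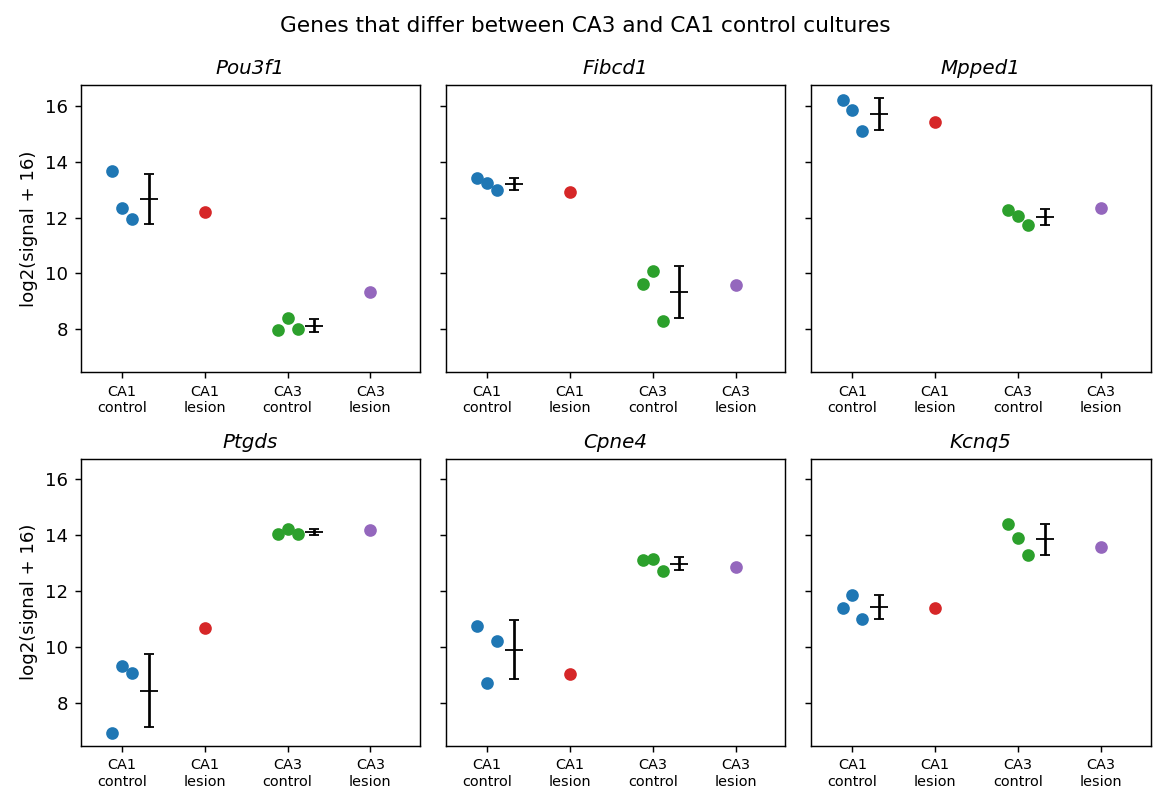
Log2 signal on each array for 3 genes higher in CA1 (top) and 3 genes higher in CA3 (bottom). Points are single arrays, black bars are the control mean ± SD (n = 3), and each lesion group is 1 array; for Ptgds the CA3 controls 1, 2 and 3 lie at 14.05, 14.24 and 14.05 and the CA1 controls at 6.94, 9.31 and 9.09.

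The marker lists for the fields separated the controls. Of 7 measured CA1 pyramidal neuron markers, 4 passed the threshold (Mpped1, Pou3f1, Fibcd1 and Gpr161), all lower in CA3, and 6 passed adjusted over the list alone. The list median was -2.29 (limma camera adjusted p = 5.38e-15, and adjusted p = 0.222 with an estimated correlation), and -2.97 without CA3 control 1. Of 6 measured CA3 markers, the adhesion molecule Nectin3 passed at 3.24-fold higher in CA3, and the kainate receptor subunit Grik4 (3.06-fold) joined it adjusted over the list alone, which gave 2. The CA3 list median was 0.83 (camera adjusted p = 0.00129, and adjusted p = 0.495 with an estimated correlation).

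Neuronal genes were higher in CA3 as a list. The 17 pan-neuronal and glutamatergic genes had a median of 0.54 (camera adjusted p = 1.94e-06, and adjusted p = 0.635 with an estimated correlation). The neurofilament gene Nefl was 2.18-fold higher in CA3, and the vesicular glutamate transporter Slc17a6 was 4.27-fold lower in CA3, both with adjusted p = 0.0277; adjusted over the list alone, 4 were higher and 1 was lower. Of 21 voltage-gated channel genes only Kcnq5 passed, also adjusted over the list alone, and the list median was 0.37 (camera adjusted p = 0.0174, and adjusted p = 0.635 with an estimated correlation). Without CA1 control 3, CA3 control 1 or CA3 control 2 the channel list had camera adjusted p-values of 0.156, 0.103 and 0.0946 and medians of 0.17, 0.15 and 0.26. With no filter the adjusted p was 0.136 (median 0.07), and with all probe sets of a gene averaged 0.0917 (median 0.09). It ran from 0.00171 to 0.635 over all alternatives. The axon guidance list did not pass (median 0.01, adjusted p = 0.146), but its members Unc5c, a netrin receptor, and Slit2, a secreted guidance cue, were 2.72-fold and 3.68-fold higher in CA3 (adjusted p = 0.0203 and 0.0367). Adjusted over the list alone, 4 guidance genes were higher and 1 was lower.

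Interneuron markers were lower in CA3 as a list, with a median of -0.41 over 10 genes (camera adjusted p = 0.00138, and adjusted p = 0.635 with an estimated correlation). Of these, 8 were lower and 2 higher, and some hardly differed. Control means in CA1 and CA3 were 14.85 and 14.82 for Gad1, 11.21 and 11.02 for Slc32a1, and 10.46 and 10.69 for Calb2. The list value therefore does not stand for every interneuron gene. Cck alone passed over all probe sets, and Cck, Vip (-1.60) and Sst (-0.76) passed adjusted over the list alone, which gave 3. Cck is also made by pyramidal cells. Without CA1 control 1 the interneuron list had a median of -0.16 and a camera adjusted p of 0.110, in a range of 5.11e-06 to 0.635 over all alternatives. Cholesterol synthesis genes had a median of 0.40 over 11 genes, of which 0 passed, also adjusted over the list alone (camera adjusted p = 0.00107, and adjusted p = 0.620 with an estimated correlation). The 8 fibroblast and meningeal markers had a median of 0.56 (camera adjusted p = 0.0128, and adjusted p = 0.635 with an estimated correlation). Ptgds passed, and adjusted over the list alone 2 did, Ptgds higher and Dcn, a matrix proteoglycan, lower (-1.99). The fibroblast list had a camera adjusted p of 0.0823 without CA1 control 1 (median 0.58) and 0.0782 without CA3 control 1 (median 0.25), in a range of 2.28e-04 to 0.635.

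The other 18 lists did not separate the fields, with camera adjusted p-values from 0.146 to 0.890. The median was -0.42 for CA2 markers, 0.10 for dentate granule cell markers, -0.21 for astrocyte markers, -0.05 for reactive astrocyte genes and -0.33 for microglia and macrophage markers. It was 0.26 for myelin and oligodendrocyte markers, 0.36 for oligodendrocyte precursor markers, -0.60 for endothelial and mural markers and 0.04 for choroid plexus and ependymal markers. Axon growth and regeneration genes had a median of 0.10, glutamate receptors -0.11, GABA receptors 0.26, immediate early genes -0.32, extracellular matrix genes 0.15, and inflammation genes -0.23. Heat shock genes had a median of 0.0024 and a mean of -0.04, and the test ran towards lower values (adjusted p = 0.829). Neurotrophins and growth factors had a median of -0.28 and a mean of -0.02 although the test ran towards higher values (adjusted p = 0.662). Adjusted over the list alone, members of 5 of these lists beside the axon guidance list passed: 3 GABA receptor genes, Gabra2, Gabbr2 and Gabra5, were higher, as were Grik4 and the choroid plexus gene Ttr (2.23), while 1 CA2 marker, Rgs14, was lower and the axon growth list had 1 gene higher and 1 lower. Of the 25 lists 7 passed, and 13 did without CA3 control 3.

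The count of 98 depended on the variance model and on single arrays. Without an intensity trend in the variances, 0 probe sets passed and 1533 had an unadjusted p under 0.05. It was 47 without CA1 control 1, 27 without CA1 control 2, 29 without CA3 control 1 and 24 without CA3 control 2, and 5 without control 1 of both fields, a setting added after the data were seen. Those 5 were Ptgds (4.94), Pou3f1 (-3.94), Mpped1 (-3.57) and a pair of probe sets with no single gene name (-2.49 and -2.28), picked out after their values were seen. All 98 kept their direction in these settings, which was likely from the start because they were picked on the same arrays.

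Lesion arrays carried more signal from microglia and myelin genes than the average control, and less from neuronal and activity-related genes, but no single gene passed in the fit with 1 coefficient per group. Genes did pass in a fit with the replicate number as a block, which is described below with its limits. Microglia and macrophage markers were 5.65-fold higher by the list median (2.50 on the log2 scale), with 13 of 13 measured members higher, among them Ly86 (2.70 ± 0.94, SE), Aif1 (2.72 ± 1.04), Fcer1g (2.27 ± 0.88) and C1qa (3.13 ± 1.26). Myelin and oligodendrocyte markers were 3.20-fold higher (median 1.68, 9 of 9 members), with Mal at 1.82 ± 0.87 and Ugt8 at 2.26 ± 1.09. Penk, which encodes the opioid peptide precursor proenkephalin, was 5.21-fold lower in the lesion arrays (-2.38 ± 0.40, SE, 2 lesion arrays against 6 controls, limma adjusted p = 0.433).

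The controls themselves differed in the medians of these glial lists, with control 1 lowest and control 3 highest in both fields. Single genes could depart from this order, and Ly86 and Aif1 were lowest in control 2 in both fields. Relative to the mean of the 8 arrays, the microglia list stood at -2.30, -0.95 and 1.34 in CA1 controls 1 to 3 and at -1.90, -1.0 and 1.40 in the CA3 controls. The lesion arrays, which carry the number 1 in the labels, stood at 2.14 in CA1 and 1.78 in CA3. In CA1 the median microglia gene exceeded control 1 by 4.37 log2 units, control 2 by 2.89 and control 3 by 0.53. In CA3 the differences were 3.44, 2.53 and 0.35. For the myelin list they were 4.14, 1.30 and 0.02 in CA1 and 2.80, 1.36 and 0.09 in CA3.

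**Figure D2:**
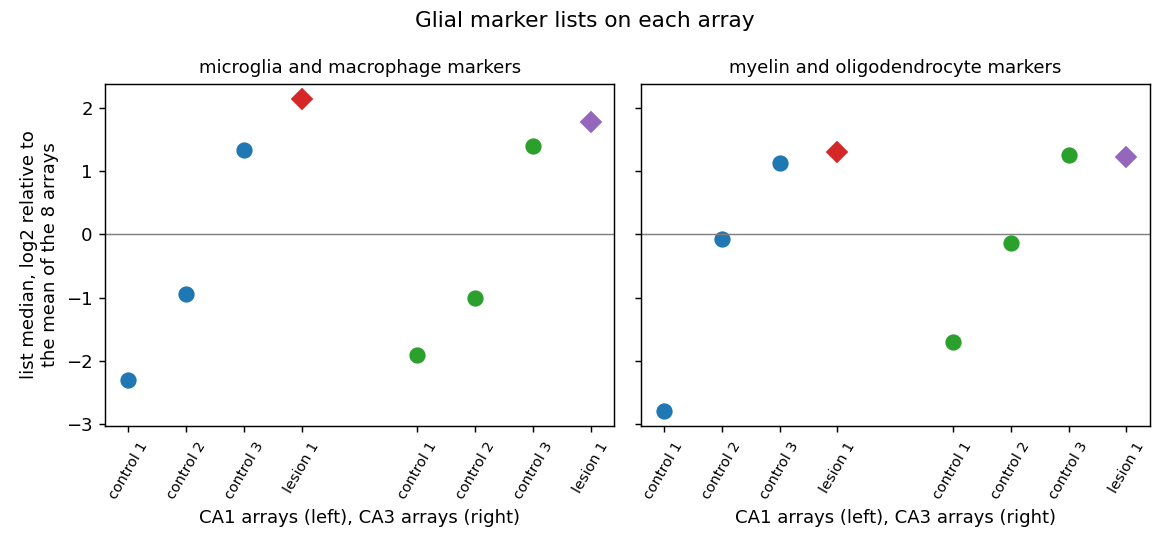
Median of the microglia and macrophage list (left panel) and of the myelin and oligodendrocyte list (right panel) on each array, in log2 units relative to the mean of the 8 arrays; circles are controls and diamonds are lesion arrays. The microglia median is 1.34 in CA1 control 3 and 2.14 in the CA1 lesion array, against -2.30 in CA1 control 1.

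In the mean lesion effect, 0 of 18625 probe sets passed in limma and 1193 had an unadjusted p under 0.05. The genes with the smallest p are named here as not past the threshold. Higher were Fam181b (0.96), the macrophage growth factor Csf1 (0.79), the kinase Clk1 (0.64), Tmem176a (1.49) and Eif4enif1 (0.74), with adjusted p-values from 0.481 to 0.771. The other probe set of Fam181b differed by -0.13, and those of Csf1 by -0.99, 0.10 and 1.04. Lower beside Penk were the smooth muscle gene Tagln (-1.23), the growth factor binding protein Igfbp3 (-1.65), Prune2 (-1.04) and the amino acid transporter gene Slc3a1 (-1.10), with adjusted p = 0.433. The other probe set of Igfbp3 differed by -2.03 and that of Prune2 by -0.17. Without CA3 control 3, Penk alone passed (-2.63, adjusted p = 0.0462). Without control 3 of both fields, a setting added after the data were seen, 182 probe sets passed, 138 higher and 44 lower.

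Of the 25 lists, 12 passed for the mean lesion effect with the preset correlation and 0 with an estimated one, where each had an adjusted p = 0.450 with an estimated correlation. Microglia markers had a camera adjusted p of 6.72e-08, myelin markers 1.45e-04, astrocyte markers 0.00132 (median 0.39, 9 genes) and inflammation and complement genes 0.00526 (median 0.80, 10 genes). In these lists 0 genes passed over all probe sets and 0 adjusted over the list alone. The astrocyte members with the smallest p were Fabp7 (0.50) and Gja1 (0.56), and the inflammation members were B2m (0.86) and Il18 (1.34). Against control 3 alone, the median astrocyte gene differed by 0.02 in CA1 and 0.07 in CA3, and the median inflammation gene by 0.04 and -0.09. Without control 1 of both fields the inflammation list had an adjusted p of 0.0780, in a range of 6.37e-06 to 0.450 over all alternatives.

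The other lists that passed were lower in the mean lesion effect, in which the microglia list was higher by 2.50. All 17 pan-neuronal genes were lower in this mean (median -0.34, camera adjusted p = 4.00e-06), 15 in CA1 and 16 in CA3, with Neurod6 at -0.77 and Rbfox3 at -0.87. Of 21 voltage-gated channel genes, 19 were lower (median -0.27, adjusted p = 4.38e-04), with Cacna1a at -1.27 and Scn2a at -0.66. Of 20 axon guidance genes, 16 were lower (median -0.25, adjusted p = 0.00107). All of these had an adjusted p = 0.450 with an estimated correlation. Against control 3 alone, the median pan-neuronal gene differed by 0.01 in CA1 and -0.09 in CA3, the median channel gene by -0.24 and -0.21, and the median axon guidance gene by 0.02 and 0.23, opposite to its mean lesion effect. Adjusted over the list alone, 0 neuronal and 0 channel genes passed, and 1 guidance gene did, Sema3e (-0.74).

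All 12 measured immediate early genes, which respond to neuronal activity, were lower in the mean lesion effect (median -0.41, camera adjusted p = 1.45e-04, and adjusted p = 0.450 with an estimated correlation), and 11 were lower in CA1 and 9 in CA3. Adjusted over the list alone 4 passed, namely Junb (-1.31 ± 0.29, SE), Ptgs2 (-1.84 ± 0.42), Egr4 (-1.73 ± 0.52) and Egr1 (-0.84 ± 0.29), and 0 passed over all probe sets. The single fields differed, with Junb at -2.52 in CA1 and -0.10 in CA3, Egr4 at -0.20 and -3.25, Ptgs2 at -1.29 and -2.40, and Egr1 at -0.70 and -0.98. In CA1 the median gene was lower by -0.22 against control 1, -0.36 against control 2 and -1.17 against control 3, and in CA3 by -0.29, -0.03 and -1.58. Without control 3 of both fields the adjusted p was 0.0813, in a range of 1.2e-06 to 0.450 over all alternatives.

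Another 4 lists passed, with medians from -0.36 to -0.22, and lost the call when single arrays were left out. For heat shock genes (median -0.22, adjusted p = 0.0235) the adjusted p was 0.0683 without CA1 control 3, 0.0525 without CA3 control 3 and 0.188 without the CA1 lesion array. For axon growth and regeneration genes (-0.23, 0.0323) it was 0.0666 without CA1 control 3, 0.0516 without CA3 control 1, 0.0896 without the CA1 lesion array and 0.0948 without the CA3 lesion array. For GABA receptors (-0.36, 0.0344) it was 0.0775 without CA1 control 1, 0.0894 without CA1 control 2, 0.0516 without CA3 control 1, 0.0828 without CA3 control 2, 0.0896 without the CA1 lesion array and 0.0706 without the CA3 lesion array. For interneuron markers (-0.25, 0.0344) it was 0.166 without CA1 control 1, 0.0689 without CA1 control 2, 0.0578 without CA3 control 2, 0.122 without the CA1 lesion array and 0.0706 without the CA3 lesion array. Each of these had an adjusted p = 0.450 with an estimated correlation, and 0 of their genes passed, also adjusted over the list alone. Against control 3 alone, the median GABA receptor gene differed by 0.10 in CA1 and -0.04 in CA3, and the median interneuron marker by 0.0046 and 0.02. Members with the smallest p were Hsph1 (-0.55), Jun (-0.38), Gabrb1 (-0.69) and Gad1 (-0.39).

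The other 13 lists did not pass for the mean lesion effect, with adjusted p-values from 0.0515 to 0.671. Reactive astrocyte genes had a median of 0.35, CA1 markers 0.02, CA3 markers -0.09, CA2 markers -0.36, dentate granule cell markers 0.36 and oligodendrocyte precursor markers 0.38. Fibroblast and meningeal markers had a median of 0.18, choroid plexus markers 0.24, glutamate receptors -0.08, neurotrophins and growth factors -0.22, extracellular matrix genes -0.03 and cholesterol synthesis genes -0.03. Endothelial and mural markers had a median of 0.14 and a mean of -0.07, and the test ran towards lower values (adjusted p = 0.286). The mean of the choroid plexus markers was -0.08, opposite to their median and test. Adjusted over the list alone, Tagln, the kainate receptor subunit Grik4 (-1.48), the matrix protein Tnc (-0.96) and the isoprenoid enzyme Idi1 (-0.97) passed, each lower.

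In CA1, glutamate receptor genes were lower in the lesion array, with 16 of 17 members lower and a median of -0.58 (camera adjusted p = 0.00110, and adjusted p = 0.460 with an estimated correlation). Microglia markers had a median of 2.76 and pan-neuronal genes of -0.37 (adjusted p = 2.12e-06 and 0.00110, and adjusted p = 0.460 and 0.481 with an estimated correlation). Adjusted over the list alone, 1 glutamate receptor gene passed, Grik4 (-2.25). In all 13 lists passed, and 6 did without CA1 control 1. Beside glutamate receptors, 3 of them did not pass for the mean effect: CA2 markers (-0.67, adjusted p = 0.0111), dentate granule cell markers (0.50, 0.0330) and endothelial and mural markers (-0.47, 0.0367), each with adjusted p = 0.460 with an estimated correlation. Without CA1 control 1 the CA2 and dentate lists had adjusted p-values of 0.109 and 0.142, and the endothelial list had 0.0923 without CA1 control 2 and 0.109 without CA1 control 3, and a median of 0.01 with no filter. In limma 0 probe sets passed and 676 had an unadjusted p under 0.05, with 3 past the threshold without control 3 of both fields, namely Pycard (4.43), Hcrt (-5.01) and a probe set with no single gene name (2.38), picked out after their values were seen. Higher without passing were Fam91a1 (1.04), Dcxr (1.49), Appl1 (0.99), Fam181b (0.97) and the cyclooxygenase Ptgs1 (1.97), and the other probe sets of Appl1 were lower, at -0.56, -0.45 and -1.29. Lower without passing were Zfp12 (-3.22), Parvb (-4.41), the transcription factor Junb (-2.52), Mir384 (-3.78) and Pgap6 (-3.32), with adjusted p-values from 0.361 to 0.396. The other probe set of Parvb differed by 0.14. Against CA1 controls 1, 2 and 3 alone, the median glutamate receptor gene of the CA1 lesion array differed by -0.64, -0.56 and -0.02.

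In CA3, the lesion array had 8 lists past the threshold, and 4 without CA3 control 1, with microglia markers at a median of 2.12 and pan-neuronal genes at -0.32 (both with camera adjusted p = 1.50e-04, and adjusted p = 0.705 with an estimated correlation). In limma 0 probe sets passed and 871 had an unadjusted p under 0.05. Closest to the threshold were the lower values of Tram1 (-3.94 ± 0.48, SE), Trex1 (-4.29 ± 0.54), Aagab (-3.40 ± 0.43) and the ubiquitin ligase Nedd4 (-3.56 ± 0.46), each with adjusted p = 0.0535, followed by Ash1l (-4.05, adjusted p = 0.178). Other probe sets of these genes lay closer to 0: that of Tram1 differed by 0.04, that of Aagab by 0.23, those of Nedd4 by -0.23, -0.12 and -0.04, and that of Ash1l by -0.44. With quantile normalisation, and with a pseudocount of 1, Tram1, Trex1, Aagab, Nedd4 and a probe set with no single gene name passed, which gave 5 in each setting. Without control 3 of both fields 6 passed, Penk (-3.08), Aagab (-3.52), Serping1 (2.54), Tspo (1.97) and a pair of probe sets with no single gene name (-1.73 and -3.10), picked out after their values were seen. Higher without passing were Cpe (0.96), Gosr1 (1.40), Ltbp3 (0.92), Rpsa (1.07) and Mbd6 (2.22), with adjusted p-values from 0.398 to 0.708. The other probe sets of Gosr1 differed by 0.07 and -0.38, and those of Rpsa by 0.24 and 0.40.

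**Figure D3:**
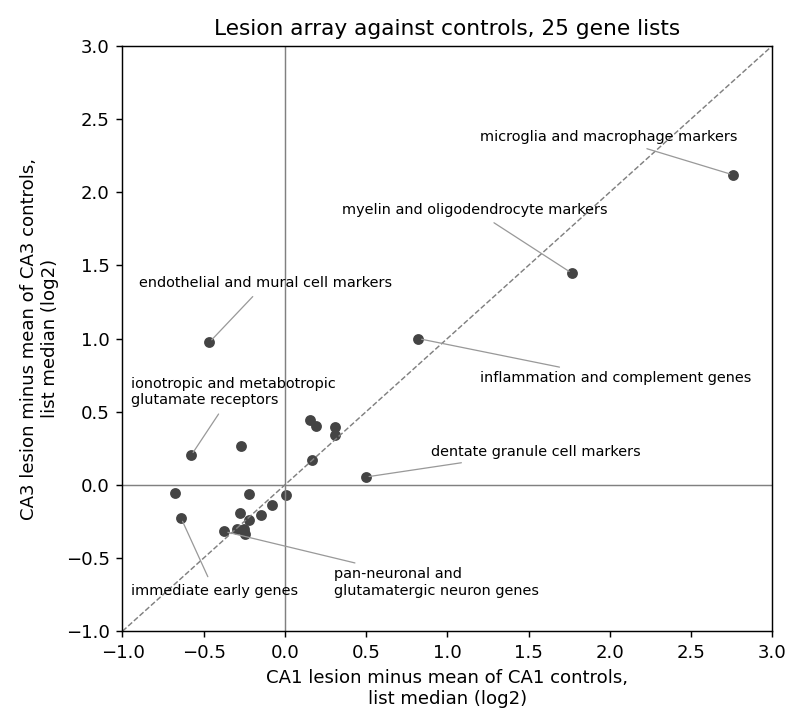
Median log2 difference between the lesion array and the mean of the 3 controls for each of the 25 gene lists, in CA1 (horizontal axis) and CA3 (vertical axis); the dashed line marks equal values. Microglia markers lie at 2.76 and 2.12, and glutamate receptors at -0.58 in CA1 and 0.20 in CA3.

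Of the 25 lists, 1 passed the test of a difference between the lesion effects in CA3 and CA1 with the preset correlation, that of the glutamate receptors, and it did not pass with an estimated one. With 1 lesion array per field, the test compares these single arrays and assumes that they vary like the controls. The lesion difference in CA3 was above that in CA1 in 16 of 17 genes, by a median of 0.39 (camera adjusted p = 0.00627, and adjusted p = 0.995 with an estimated correlation), with Grin2c at 1.33, Grik4 at 1.54, Grm4 at 1.49 and Grin2b at 1.83. Of these 17 genes, 0 passed over all probe sets and 0 adjusted over the list alone. Without CA3 control 3 the adjusted p was 0.141, and with a filter at the 60th percentile it was 0.171, in a range of 6.45e-04 to 0.995 over all alternatives. Without CA1 control 3, 4 lists passed, and without CA3 control 3, 0 did. For single genes 0 probe sets passed in limma and 576 had an unadjusted p under 0.05. Named without passing were Zfp12 (4.03), Pgap6 (3.87), Deaf1 (2.06), Nomo1 (1.66) and Add1 (2.69), higher in the CA3 effect, and Trex1 (-5.22), Tram1 (-4.14), Aagab (-3.50), Nedd4 (-3.47) and Gask1b (-3.32), lower. Other probe sets differed by 0.17 for Add1, -0.10 for Tram1, 0.14 for Aagab, and -0.08, -0.43 and 0.05 for Nedd4.

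Across the 18625 probe sets, which are not independent replicates, the lesion effects in CA1 and CA3 correlated at r = 0.155 (Spearman's rho 0.183), and 57.8% had the same sign. When every array in turn stood in for the lesion array of its field, 4 of the 16 pairings, the real one included, gave a correlation as large. The reference was then the other arrays of the field, the real lesion array among them. The CA1 lesion array paired with CA3 controls 1, 2 and 3 gave -0.21, -0.12 and 0.19. CA1 controls 1, 2 and 3 paired with the CA3 lesion array gave -0.21, -0.05 and 0.12. Control arrays with the same number gave 0.08 to 0.24 and those with different numbers -0.19 to 0.13. With a filter at the 60th percentile, which left 12417 probe sets, the correlation of the lesion effects was 0.39, and 3 of the 16 pairings gave one as large. Control arrays with the same number then gave 0.25 to 0.48 and those with different numbers -0.40 to 0.24.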

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

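The comparison with each single control below was chosen after the result was seen. The difference of the lesion effects between CA3 and CA1 was tested for all 25 lists, and 1 list passed with the preset correlation and 0 with an estimated one. Glutamate receptor genes had a median difference of 0.39 on the log2 scale (camera adjusted p = 0.00627, higher in 16 of 17 genes), and over the alternatives the median ran from 0.30 to 0.76, with the call lost in 3 of 18 alternatives and adjusted p-values from 6.45e-04 to 0.995. The CA1 lesion array differed from CA1 controls 1, 2 and 3 by a median of -0.64, -0.56 and -0.02, and the CA3 lesion array differed from its controls by 0.02, 0.06 and 0.36.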

How the results depend on the processing

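The fits without control 1 or control 3 of both fields, and the count over other splits of the control arrays, were chosen after the data were seen. The 98 probe sets that differed between CA3 and CA1 controls kept their direction in every alternative that tested them. They were picked on these same arrays, so a change of direction was unlikely from the start. The number of probe sets past the threshold ran from 24 to 104 with single arrays left out. It was 0 without an intensity trend and 5 without both controls 1. Of the 10 splits of the 6 control arrays, the real one gave 109 probe sets and the highest other 0, and 10 splits are too few for a share under 0.05. By an unadjusted limma p under 0.05, the real split had 1566 probe sets. The split of CA1 control 1, CA3 control 1 and CA3 control 2 from the other control arrays had 1921. The field was therefore not the only structure among the controls. With 1 array left out, 0 to 1 probe sets passed for the mean lesion effect, 5 to 13 lists for the region contrast, 6 to 14 for the lesion in CA1, 4 to 9 for the lesion in CA3 and 0 to 4 for the difference of the lesion effects. Without both controls 3, 182 probe sets passed for the mean lesion effect, 3 in CA1 and 6 in CA3, and without both controls 1, 7 lists passed in CA1. Quantile normalisation and a pseudocount of 1 each gave 5 in CA3. With an estimated correlation, 0 lists passed in any contrast. Averaging all probe sets of a gene left 4 lists in CA3. A filter at the 60th percentile left 0 lists for the difference of the lesion effects and moved the correlation of the lesion effects from 0.15 to 0.39. The cause of these shifts was not tested. Of the alternatives for the lists that passed, 649 kept the call and 146 lost it, and 0 changed the direction of the test, although the median of the endothelial list in CA1 went from -0.47 to 0.01 with no filter. Without a filter the median difference of all probe sets was 0.11 for the lesion in CA3 and 0.12 for the difference of the lesion effects, against 0.05 and 0.01. The arrays carry no measure of signal over background that was used here, so the limit for dim probe sets is not known.

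The replicate number as a block gave 358 probe sets for the region contrast, 697 for the mean lesion effect, 258 in CA1, 310 in CA3 and 0 for the difference of the lesion effects, where 2 lists passed, and a correlation of the lesion effects of 0.44. By its construction this fit sets the lesion arrays, numbered 1, against the level of controls 1, from which they differed most in the microglia and myelin lists, and a mislabelled set would change its meaning. Same-numbered controls deviated together with r = 0.16, 0.06 and 0.31, and each control correlated best with its own number in the other field, which is a hint from the data and not from the design. One pair lay under 0.1, so the numbers were not taken to pair the samples, although the controls differed by number in 464 probe sets and whether the numbers mark shared cultures remains open.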

Other observations

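The tests in this part were chosen after the results they concern had been seen, except the test of activity-regulated genes, whose list was written before the values of those genes were looked at. The 6 control arrays differed by replicate number in a fit over both fields. In this limma model with field and number, 464 of 18625 probe sets passed for the number, with 2 residual degrees of freedom, among them 10 of 13 microglia markers, 9 of 9 myelin markers and 6 of 12 reactive astrocyte genes. Mean log2 values in controls 1, 2 and 3 were 9.29, 11.33 and 14.56 for the complement gene C1qc and 8.87, 10.56 and 14.00 for C3. The acute-phase gene Lcn2 was highest in control 3, at 14.45 in CA1 and 14.65 in CA3, while controls 1 and 2 stood at 9.54 and 8.04 in CA1 and at 6.86 and 10.38 in CA3. The myelin tight-junction gene Cldn11 stood at 12.09, 14.66 and 16.55. The chemokine gene Ccl2 was highest in control 3, at 14.45, against 11.53 and 10.18, and stood at 11.85 and 11.93 in the CA1 and CA3 lesion arrays.

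Other genes were highest in control 1. Sprr1a, a gene induced in injured neurons, had mean log2 values of 13.20, 6.02 and 9.54 in controls 1, 2 and 3 (adjusted p = 2.82e-04). The acute-phase gene Serpina3n stood at 12.85, 8.37 and 9.95 (adjusted p = 2.64e-04). In the lesion arrays Sprr1a was 8.01 in CA1 and 8.85 in CA3, and Serpina3n was 9.74 and 8.15.

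The higher microglia and myelin signal of the lesion arrays was tested against 3 candidate explanations. A lower share of neurons would raise all glial markers alike, but the median microglia marker exceeded the median astrocyte marker by 2.10 log2 units. The difference of their means had an exact permutation p of 1.01e-05 (2-sided, 13 against 9 genes, which are not independent). That test permutes genes and does not measure the spread between arrays, so its p is not counted here. The gap of the medians argues against a lower share of neurons as the whole cause. A difference between culture sets that the controls show as well remains open: the list medians of the lesion arrays exceeded the highest control of their field by at most 0.80, less than 1 SD of the controls. The lesion remains open too, since 12 of 13 microglia markers, though only 5 of 9 myelin markers, lay above all controls of their field in both lesion arrays, and with 1 lesion array per field it cannot be told apart from culture-to-culture differences. A mislabelled set was not tested and remains open, since the lesion arrays carry the number 1 but differed from control 1 by 4.37 in CA1 and 3.44 in CA3 in the median microglia marker, and from control 3 by 0.53 and 0.35.

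Some probe sets were far lower in a single lesion array. More than 2 log2 units below all 7 other arrays lay 69 probe sets in the CA1 lesion array and 95 in the CA3 lesion array, and 39 to 157 in the control arrays, so a low signal estimate on single arrays may account for them. The 70 other probe sets of the genes of 48 such probe sets had a median lesion difference of -0.15, against -3.34 for the low ones. Of the 70, 10 were lower by over 1 log2 unit, and 2 of these are themselves among the low ones. The low ones were picked for their low values on the same array, so part of this gap was set by the choice. Most of the other probe sets did not share drops of this size, which does not exclude the lesion for single genes. Among probe sets with an unadjusted p under 0.01, 87.4% were lower in the CA1 lesion array and 90.5% in the CA3 lesion array, and with each control in place of the lesion array 39.2% to 94.8% were lower.

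Ptgds, higher in CA3 by 5.66 log2 units, is expressed in meninges and oligodendrocytes, so tissue carried along in dissection is a candidate source. The other 7 fibroblast and meningeal markers had a median difference of 0.37 (SD 1.05), and the 9 myelin markers 0.26 (SD 0.45). Both lie far below the Ptgds difference, but carried tissue would move a marker less where its level is already high. CA1 control means were 8.45 for Ptgds and 9.22 (Igf2) to 11.50 (Postn) for the other fibroblast markers, which limits their weight against meningeal tissue. Igf2, the closest in level to Ptgds, had a mean of only 9.42 in the CA3 controls. Dcn had means of 10.68 in CA1 and 8.69 in CA3, a drop that carried tissue alone would not give. Of the 8 fibroblast and meningeal markers, Ptgds included, 7 were higher in CA3 and 1 was lower. In CA3 controls 1 to 3 the myelin list stood at -1.70, -0.14 and 1.25 relative to the mean of the 8 arrays, and Ptgds at 14.05, 14.24 and 14.05. These values argue against more oligodendrocytes as the whole cause. The choroid plexus marker Ttr was 2.23 higher in CA3 (adjusted p = 0.187, and 0.00738 adjusted over the list alone), while Folr1 and Foxj1 differed by -0.39 and 0.04. Ttr stood at 11.04, 11.44 and 13.53 in the CA3 controls, 9.97 in the CA1 lesion array and 10.07 in the CA3 lesion array, where Ptgds, measured by 1 probe set, stood at 14.19. Meningeal tissue, choroid plexus tissue and a difference between the fields themselves remain open and were not tested apart.

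The immediate early gene list was lower in the mean lesion effect, although 1 of 12 genes, Ier2, was higher in CA1 and 3, Arc, Nr4a1 and Fosb, were higher in CA3, and the list had an adjusted p = 0.450 with an estimated correlation and 0.0813 without control 3 of both fields. Picked after their values were seen, Penk was 5.21-fold, Adcyap1 8.16-fold, Scg2 1.89-fold and Bdnf 1.88-fold lower. Their limma adjusted p-values were 0.433, 0.485, 0.438 and 0.771, so none passed. Among neuropeptide genes of the interneuron list, Sst stood at 0.07, Cck at -0.03, Vip at -0.31 and Npy at -0.97. A hypothesis is that activity-driven transcription was lower in the lesion arrays. A list of 21 other activity-regulated genes, of which 14 were measured, had a median of -0.33, beside -0.34 for pan-neuronal genes and 2.50 for microglia markers, with 9 genes lower, among them Nrn1 (-0.73) and Inhba (-2.15), while Per1 stood at 0.61. Camera gave an unadjusted p of 0.00153 with the preset correlation and 0.127 with an estimated one, and 0 genes passed over all probe sets, so the hypothesis remains open.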
